A study of Homo sapiens with 12 samples.

How the data were processed

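RNA was measured in primary human trophoblasts from 2 term placentas. Per the labels, the cells were plated on plastic, and 24 h later they received 10 Gy from a 6 MV photon beam at 250 cGy/min or a sham treatment. RNA was taken 4, 8 and 24 h after that with a kit that isolates total RNA. Each of the 6 groups of treatment and time held 2 arrays, and the replicate number named the placenta, so that 1 array of every group came from each placenta. The pairing was checked on the values: for each of the 15 pairs of groups, the deviation of a gene from its group mean correlated across genes with r = 0.511 to 0.749.

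Each RNA was labelled with Cy3 and hybridized to a one-colour Agilent array annotated on hg19. Per the file headers, the scanner files were made by Agilent Feature Extraction 10.7.3.1, and their processed signal is an intensity with the background subtracted and a spatial trend removed, not scaled between arrays. The raw median signal and the median of the local background in the same files are intensities too, per the file headers. The deposited matrix holds log2 values that are a smooth curve of the log2 processed signal of the same array, with column medians of 5.06 to 5.18; the submitters' processing notes name R 2.15.1 and the affy package, and the normalization behind the matrix is not given in the sources used here. Each array had 62976 spots, of which 4259 were controls, and 42405 probes. A gene symbol was given for 24910 probes (19102 genes), and the other 17495 probes had none. The 76 probes for genes on the Y chromosome, XIST and TSIX were left out of every table. Spots marked by the scanner program as nonuniform or as population outliers, 298 to 451 per array, were dropped, which left 184 probe values missing; probes with a missing value were left out.

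The log2 processed signal was reduced by the 75th percentile of its array, and spots of a probe were averaged. A gene was represented by its probe with the highest mean over the 12 arrays, since 3881 of the genes tested had more than 1 probe. A gene was kept if this probe was well above background on both arrays of at least 1 group, which left 13412 of 19010 genes. Between 21944 and 24836 probes per array were well above background and 0 were saturated. The number of arrays, 2 per group, limits the precision of every value, and the p-values describe these 2 placentas.

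Group means were fitted with limma 3.58.1 (R 4.3.3) over all 12 arrays, with a variance prior that follows the mean signal. This fit held no term for the placenta, so the difference between the placentas entered its standard errors and p-values. Tests of genes given without an alternative named are from this fit. The fit with the placenta as block takes that difference out. The comparisons were irradiated minus sham at 4, 8 and 24 h and as the mean of the 3 times, the irradiation effect at 24 h or at 8 h minus that at 4 h, and sham at 24 h minus sham at 4 h. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene passed the test at an adjusted p under 0.05. Errors beside log2 differences are limma's moderated standard errors (SE), and n counts arrays. A gene that was not well above background on any array of one side has its fold given as a lower bound, from that side's background limit. On simulated data with the real spread and 200 changed genes in 20 simulations, the test at a single time found most of the 4-fold changes and a minority of the 2-fold changes. It found 34.7% to 35.15% of the 2-fold changes, and 0.319% to 0.628% of its calls were false. With the placenta as block 73% to 74.5% were found, and 4.33% to 4.9% of the calls were false. Each simulated gene held a constant difference between the placentas, as the block assumes.

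Lists of genes were fixed for p53 targets, G2 and mitosis, S phase and replication, DNA double-strand break repair, replication-dependent histones, syncytiotrophoblast, villous cytotrophoblast, extravillous trophoblast, cell death outside the p53 list, NF-kB and cytokines, interferon-stimulated genes, hypoxia, the unfolded protein and ATF4 response, oxidative stress and NRF2, heat shock, immediate early genes, and markers of placental fibroblasts, endothelium, macrophages and leukocytes, erythroid cells, and decidua and amnion. Some genes are on more than 1 list. The histone list also holds the linker histone gene H1-0, which is not replication-dependent, so its name does not hold for every member. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data; adjusted p-values printed beside a list's median are those of the preset correlation unless the estimated correlation is named. On simulated data, 20 of 20 lists of 30 genes raised by 0.5 in log2 were found, and 1 of 380 unchanged lists was called. The simulated genes varied independently of each other and held no difference between placentas. These rates therefore do not apply to lists whose members vary together. The correlation estimated from the data ranged from -0.04 for fibroblast markers to 0.63 for interferon-stimulated genes.

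The comparisons, the lists and the rule for naming genes were chosen before the data were examined. The rule took, in each comparison, the 12 highest and the 12 lowest log2 differences among genes that passed and went the same way in both placentas (6 and 6 for the differences between times); where fewer than 6 genes passed, the 10 with the smallest p, given as values; up to 4 members of each list with the smallest p; and always CDKN1A, MDM2, TP53, BAX, FAS, GDF15, CCNB1, MKI67, CGA, ERVW-1, CYP19A1, HLA-G and VIM.

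The alternatives were quantile normalization, the submitters' matrix, a normexp background correction with an offset of 50, no filter, a filter on all 12 arrays, every probe tested, no trend in the variance prior, the placenta as a covariate, the slide as a covariate, both, the arrays of slide 2 alone, only the arrays compared, and each array left out in turn. The fits with an array left out held no placenta term, so that the difference between the placentas entered their comparisons. The normexp version planned on mean signals was not run, since the files hold no such column, and median signals took its place after the files were seen. An exact sign-flip test over the 6 irradiated and sham pairs and a test of probes without a gene symbol were also added then.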

Results

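Expression was measured on 12 one-colour arrays in primary human trophoblasts, the epithelial cells of the placenta, from 2 term placentas. The cells had been in culture for 24 h when they received 10 Gy of ionizing radiation or a sham treatment, and RNA was taken 4, 8 and 24 h later. There were 6 groups of 2 arrays, 1 array from each placenta. Of the 42405 probes on an array, 51.7% to 58.6% were well above background, and 13412 genes entered the tests. The number of arrays limits the precision.

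Hours in culture and the placenta of origin separated the arrays more than irradiation did. The first principal component held 39.1% of the variance and placed the 24 h arrays, between 37.1 and 44.8, apart from the 4 h arrays, between -35.3 and -23.0. The second held 30.9% and separated the placentas. The third held 6.72%, and the 6 sham arrays had positive scores, from 4.39 to 15.4, while the 6 irradiated arrays had negative ones, from -20.9 to -2.84. Across genes, which are not independent replicates, arrays of the 2 placentas within a group correlated with r = 0.981 to 0.984, and the irradiated and sham arrays of the same placenta and time with r = 0.990 to 0.995. The 4 arrays of placenta 1 at 4 h and 8 h were on slide 1 and the other 8 on slide 2, so that every irradiated array shared its slide with its sham partner. Sham arrays lay in columns 1 and 3 of a slide and irradiated arrays in columns 2 and 4, so treatment and column are confounded in every comparison of irradiated with sham arrays.

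**Figure D1:**
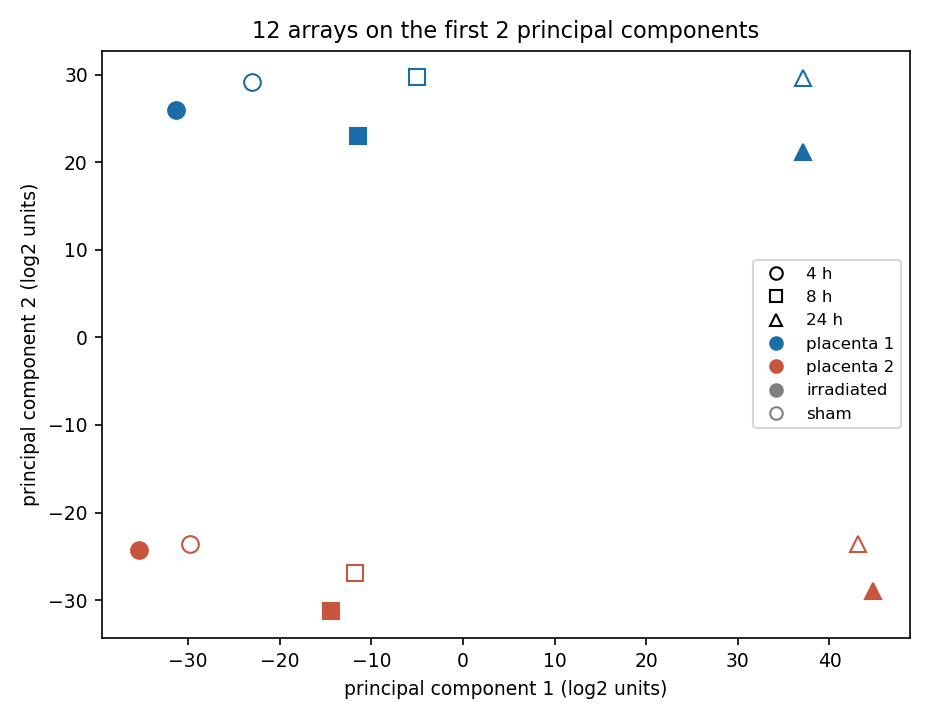
Scores of the 12 arrays on the first and second principal components of the log2 signal (log2 units), with 1 point per array, marked by treatment, time and placenta. The 24 h arrays lie between 37.1 and 44.8 on the first component, right of all others, and the second component separates the 2 placentas.

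The comparison at 4 h asks which transcripts of the trophoblast change first after 10 Gy. Genes activated by the tumour suppressor p53 rose. EDA2R, a receptor of the tumour necrosis factor receptor family, rose 5.04-fold (log2 2.33 ± 0.19, SE, n = 2 arrays per group, adjusted p = 0.0122). MDM2, the ubiquitin ligase that degrades p53, rose 4.18-fold (2.06 ± 0.22, adjusted p = 0.0203), and CDKN1A, the cell cycle inhibitor p21, 4.05-fold (2.02 ± 0.22, adjusted p = 0.0245). The receptors for the death ligand TRAIL TNFRSF10D and TNFRSF10B rose 3.52-fold and 2.38-fold (adjusted p = 0.0203 and 0.029), the exonuclease gene AEN 3.06-fold, and DDB2, which recognizes damaged DNA, 2.56-fold (both adjusted p = 0.016).

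These 7 genes were all that passed by limma at 4 h, and 0 genes fell; 598 had an unadjusted p under 0.05. With the placenta as block 67 genes rose and 24 fell, 26 of the 67 on the p53 list. Of the 53 p53 targets tested, 50 were higher, with a median log2 difference of 0.68 (adjusted p = 2.94e-49; adjusted p = 0.00116 with an estimated correlation); 6 rose when adjusted over all genes and 34 when adjusted over the list alone. The median of the list was 0.81 in placenta 1 (slide 1) and 0.68 in placenta 2 (slide 2). FAS, the receptor of the Fas death ligand, was at 1.75 (adjusted p = 0.626) and rose in the fit with the placenta as block (adjusted p = 0.000638), as did GDF15, a secreted stress cytokine, at 0.48 (adjusted p = 0.0414). BAX, a pore-forming protein of apoptosis, was at 0.60 and did not pass.

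The G2 and mitosis list was lower at 4 h. Of its 39 members tested, 37 were lower, with a median of -0.56 (adjusted p = 1.23e-21; adjusted p = 0.0379 with an estimated correlation), or -0.65 in placenta 1 and -0.53 in placenta 2. The call was lost with the placenta as block and an estimated correlation together (adjusted p = 0.178). By limma 0 members fell when adjusted over all genes and 0 when adjusted over the list alone; with the placenta as block 0 fell over all genes and 14 over the list alone. The centromere protein CENPF was at -1.08 ± 0.27, the cyclin CCNA2 at -1.04 ± 0.31 and the spindle motor KIF11 at -0.89 ± 0.25. The S phase and replication list was lower at 27 of 30 members, with a median of -0.17 (adjusted p = 0.00491; adjusted p = 0.375 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Its test did not pass without the irradiated 4 h array of placenta 1 (adjusted p = 0.682) or the sham 4 h array of placenta 2 (adjusted p = 0.108).

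NF-kB and cytokine genes rose as a list at 4 h, where 19 of 20 were higher with a median of 0.40 (adjusted p = 1.11e-08; adjusted p = 0.228 with an estimated correlation). When adjusted over all genes 0 of them passed, with the placenta as block 2 did, and 3 passed when adjusted over the list alone. LIF, a cytokine of the interleukin 6 family, was at 1.58, the chemokine CXCL1 at 0.90 and RELB, a subunit of NF-kB, at 0.53. BIRC3, an inhibitor of apoptosis, was at 1.14 (adjusted p = 0.748) and rose in the fit with the placenta as block (adjusted p = 0.0241). The immediate early list, with a median of 0.08, was not called (adjusted p = 0.0738) but was with the placenta as block (adjusted p = 0.0199; adjusted p = 0.435 with the block and an estimated correlation). TRIB3, a pseudokinase of the ATF4 response, was at -0.74 (adjusted p = 0.115) and fell in that fit (adjusted p = 0.014).

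The count of 7 genes at 4 h moved with single arrays. Those fits held no placenta term and left 1 array in a group. Without a 4 h array the difference between the placentas entered the comparison. Without an array of another time less was left to estimate the spread from. A lost call there does not show an unstable irradiation effect. It was 0 without the irradiated 4 h array of placenta 1 or either irradiated 8 h array, and 1 without either sham 4 h array. Without either sham 8 h or either sham 24 h array it was 4 (AEN, DDB2, EDA2R and MDM2 each time). The single genes, chosen after their values were seen, were POLR1A at -2.65 without the sham array of placenta 1 and RIT1 at 1.93 without that of placenta 2. None of the 7 calls held without every one of the 12 arrays in turn, and with the slide as a covariate the count was 24, all higher.

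**Figure D2:**
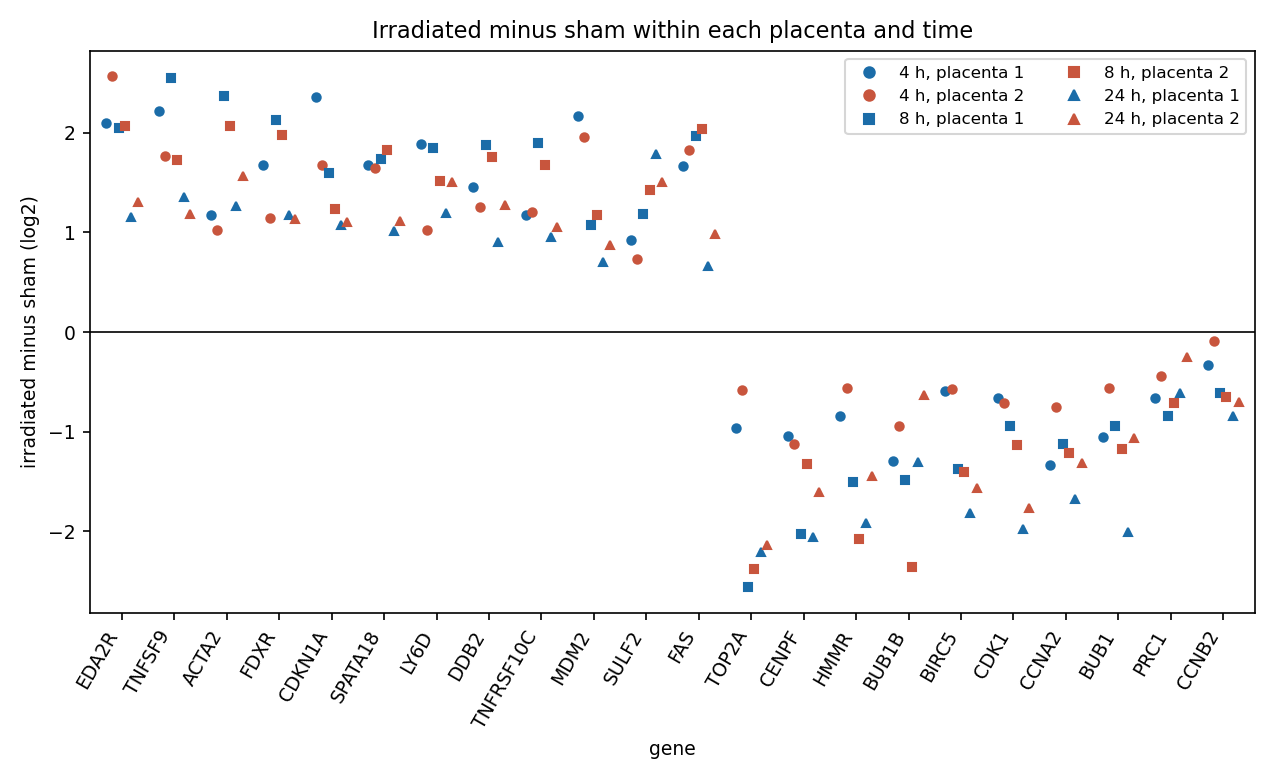
Log2 difference between the irradiated and the sham array of the same placenta for 22 genes, with 1 point for each of the 6 pairs (2 placentas at 4, 8 and 24 h). CDKN1A, MDM2, EDA2R and DDB2 lie above 0 in all 6 pairs, and CENPF and BIRC5 below 0 in all 6.

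At 8 h the p53 targets were again higher, joined by ACTA2, the smooth muscle actin gene, which rose 4.66-fold (log2 2.22 ± 0.25, n = 2 arrays per group, adjusted p = 0.0255). EDA2R rose 4.17-fold (2.06 ± 0.19, adjusted p = 0.00834), FDXR, a mitochondrial ferredoxin reductase, 4.14-fold (2.05 ± 0.21, adjusted p = 0.0198), DDB2 3.53-fold (1.82 ± 0.13, adjusted p = 0.00328) and the TRAIL decoy receptor TNFRSF10C 3.45-fold (1.79 ± 0.16, adjusted p = 0.00834). ELAPOR1 rose 2.30-fold (1.20 ± 0.14, adjusted p = 0.0347) and the ribosomal protein gene RPS27L 1.98-fold (0.99 ± 0.09, adjusted p = 0.00834). The olfactory receptor gene OR4K17 was at least 5.64-fold lower (adjusted p = 0.0347), since it was above background on the sham arrays at 8 h and on no irradiated one; the sham arrays at 4 h and 24 h were at background too.

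Of 53 p53 targets 49 were higher at 8 h, with a median of 0.49 (adjusted p = 2.47e-39; adjusted p = 0.00227 with an estimated correlation), 0.51 in placenta 1 and 0.47 in placenta 2. Over all genes 5 rose, and 21 adjusted over the list alone. CDKN1A at 1.42 (adjusted p = 0.169), MDM2 at 1.13 (adjusted p = 0.278) and FAS at 2.00 (adjusted p = 0.448) did not pass and rose in the fit with the placenta as block (adjusted p = 0.0128, 0.000963 and 0.000294). In that fit 59 genes rose and 20 fell, 21 of the 59 on the p53 list and 9 of the 20 on the G2 and mitosis list, against 7 and 1 without the block; 381 genes had an unadjusted p under 0.05 in the latter.

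G2 and mitosis genes were also lower at 8 h, with a list median of -0.82 and 36 of 39 lower (adjusted p = 1.26e-48; adjusted p = 0.00435 with an estimated correlation), or -0.94 in placenta 1 and -0.71 in placenta 2. It was not called with the block and an estimated correlation together (adjusted p = 0.0622). By limma 0 members passed over all genes, 21 passed adjusted over the list alone, and 9 fell with the placenta as block. In the blocked fit the topoisomerase TOP2A was at least 4.36-fold lower (adjusted p = 0.0101), CENPF was at -1.68 (adjusted p = 0.0101), BIRC5, survivin, at -1.39 (adjusted p = 0.00303) and the spindle factor TPX2 at -1.16 (adjusted p = 0.043). Without the block their adjusted p-values were 0.149 to 0.238. The S phase list was lower at 25 of 30 members, with a median of -0.18 (adjusted p = 0.000299; adjusted p = 0.345 with an estimated correlation); 0 members fell over all genes, 0 fell adjusted over the list alone and 1 rose there. That member was TYMS, thymidylate synthase, at 1.23 (adjusted p = 0.196, and 0.00768 with the placenta as block). DNA double-strand break repair genes had a median of -0.11, with 24 of 28 lower (adjusted p = 0.000869; adjusted p = 0.265 with an estimated correlation) and 0 members passing over all genes or adjusted over the list alone. Their test did not pass without the sham 8 h array of placenta 1 (adjusted p = 0.107) or the irradiated one of placenta 2 (adjusted p = 0.23).

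With the placenta as block, 2 more lists were called at 8 h: interferon-stimulated genes, with a median of -0.20 (adjusted p = 0.0119 against 0.0697), and syncytiotrophoblast genes, with a median of 0.14 (adjusted p = 0.0488 against 0.373). Both calls were lost with the block and an estimated correlation (adjusted p = 0.596 and 0.551). The count of 8 genes at 8 h also moved when an array was left out, in fits with the same limits as at 4 h. The count was 0 without the irradiated 8 h array of placenta 2. It was 4 without either sham 4 h array, either sham 24 h array or the irradiated 8 h array of placenta 1, 5 without either irradiated 4 h array, and 12 without the sham 8 h array of placenta 1. Among these, DDB2, EDA2R, RPS27L and TNFRSF10C were the 4 genes without a sham 4 h or a sham 24 h array; FDXR joined them without an irradiated 4 h array. DDB2, FAM223B, FOXP2 and XXYLT1, the last 3 chosen after their values were seen, were the genes without the irradiated 8 h array of placenta 1. With the slide as a covariate the count was 24, and 0 of the 8 calls held without every array.

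At 24 h, 0 genes passed by limma without a placenta term (smallest adjusted p = 0.121), with 303 genes at an unadjusted p under 0.05. With the placenta as block 42 genes passed. DDB2 was at 1.09 ± 0.13 (adjusted p = 0.121), EDA2R at 1.23 ± 0.19, TNFRSF10C at 1.00 ± 0.16 and RPS27L at 0.64 ± 0.09 (n = 2 arrays per group). CDK1, the mitotic kinase, was at least 3.14-fold lower (adjusted p = 0.121), BIRC5 was at -1.69 ± 0.22, CENPF at -1.83 ± 0.27, and the mitotic cyclin CCNB2 and the securin gene PTTG1 both at -0.77 ± 0.12. The mitotic kinase gene PBK was not well above background on either side, so that no fold is given. With the placenta as block 22 genes rose and 20 fell, among them all of these (adjusted p between 0.00331 and 0.0233), with 10 of the 22 on the p53 list and 7 of the 20 on the G2 and mitosis list. With the slide as a covariate 2 genes passed, BIRC5 (adjusted p = 0.0438) and the sulfatase gene SULF2 at 1.65 (adjusted p = 0.0484), although the 4 arrays at 24 h shared slide 2. CDK1 passed without a trend in the variance prior (adjusted p = 0.0248), and TRIM66, chosen after its values were seen, without the sham 24 h array of placenta 2, which left a sham array at background.

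As lists, p53 targets were still higher at 24 h and G2 and mitosis genes lower. Of 53 p53 targets 44 were higher, with a median of 0.23 (adjusted p = 1.25e-21; adjusted p = 0.00618 with an estimated correlation) and 0.26 in each placenta; 0 rose over all genes and 11 adjusted over the list alone. MDM2 was at 0.79 (adjusted p = 1, and 0.0166 with the placenta as block), CDKN1A at 1.09 and FAS at 0.83. Of 39 G2 and mitosis genes 35 were lower, with a median of -0.82 (adjusted p = 8.22e-50; adjusted p = 0.00618 with an estimated correlation), -0.94 in placenta 1 and -0.60 in placenta 2. The block and an estimated correlation together ended this call (adjusted p = 0.0653). By limma 0 of them fell over all genes, 7 with the block and 20 adjusted over the list alone. With values at background set to the background limit (9 members were at background on one side only and 6 on both), that median was -0.72.

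Interferon-stimulated genes fell as a list at 24 h. All 24 members tested were lower, with a median of -0.70 (adjusted p = 1.9e-15; adjusted p = 0.424 with an estimated correlation), -0.75 in placenta 1 and -0.68 in placenta 2. By limma 0 members passed over all genes and 0 adjusted over the list alone; with the placenta as block 0 passed over all genes and 20 adjusted over the list alone. RSAD2 (viperin) was at -0.70 ± 0.20, the mitochondrial kinase CMPK2 at -0.70 ± 0.22, the transcription factor IRF7 at -0.54 ± 0.15 and the membrane protein IFITM1 at -0.96 ± 0.33. The macrophage and leukocyte list had a median of -0.07 (adjusted p = 0.501) and decidual and amnion markers -0.05 (adjusted p = 0.223). Among the latter KRT17 and KRT14, both at -0.66, did not pass and fell in the fit with the placenta as block (adjusted p = 0.0357 and 0.0394).

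The histone list was higher at 15 of 19 members at 24 h, with a median of 0.18 (adjusted p = 0.00485, and 0.651 with an estimated correlation). Over all genes or adjusted over the list alone, 0 members passed. The call ended without the sham 24 h array of placenta 1 (adjusted p = 0.667) or the irradiated one (adjusted p = 0.0563). H4C3 was at -0.40, and the probes for H2AC6 disagreed, at -0.08 and 0.28. The S phase list had a median of -0.11 with 21 of 30 lower (adjusted p = 0.0106; adjusted p = 0.612 with an estimated correlation) and 0 members passing over all genes or adjusted over the list alone. It was not called without the sham 24 h array (adjusted p = 0.299) or the irradiated 24 h array (adjusted p = 0.386) of placenta 1.

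**Figure D3:**
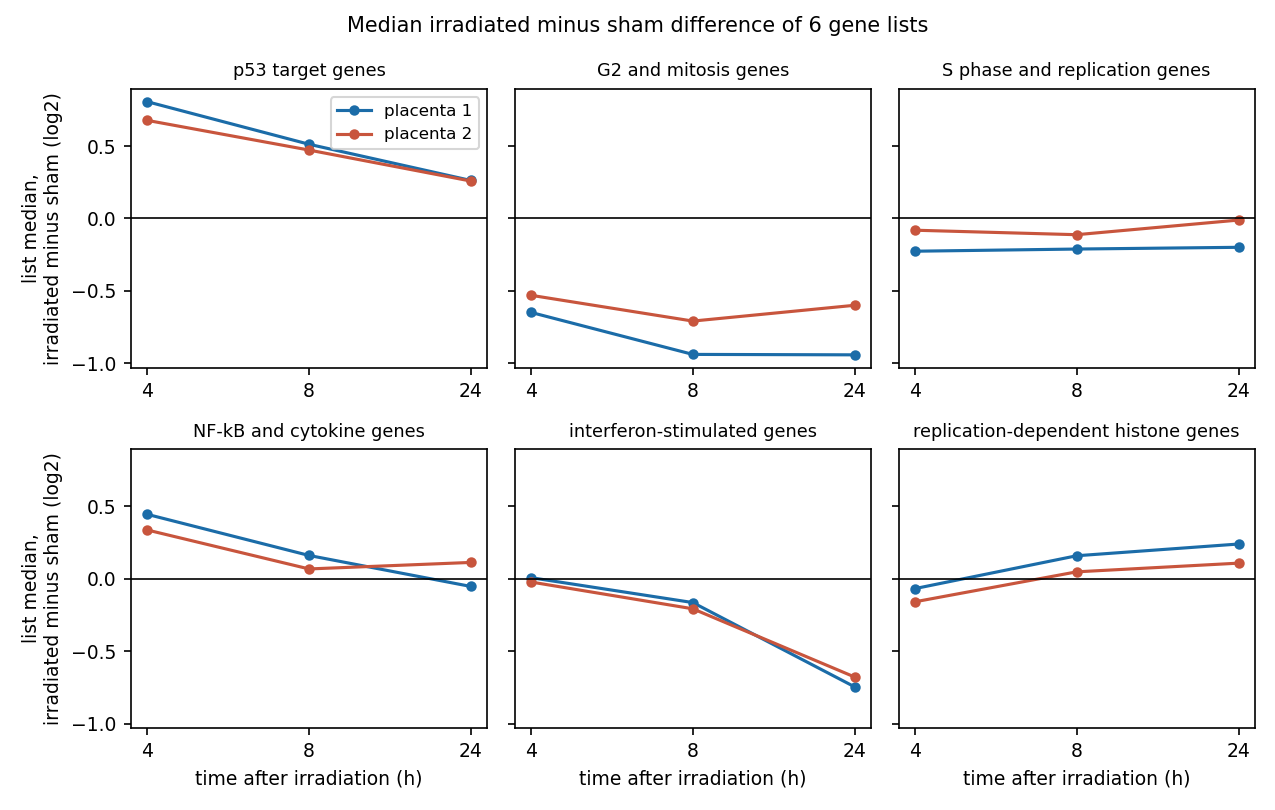
Median log2 difference between irradiated and sham arrays over the members of 6 gene lists at 4, 8 and 24 h, with 1 point per placenta. The p53 list lies above 0 and the G2 and mitosis list below 0 at each time in both placentas, and the interferon-stimulated genes are at -0.75 and -0.68 at 24 h.

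Averaged over the 3 times, 6 irradiated against 6 sham arrays, 33 genes rose and 19 fell. EDA2R rose 3.67-fold (log2 1.87 ± 0.11, adjusted p = 0.000401), ACTA2 2.99-fold (1.58 ± 0.14, adjusted p = 0.00327), and FDXR 2.90-fold (1.54 ± 0.12, adjusted p = 0.00203). CDKN1A rose 2.85-fold (1.51 ± 0.13, adjusted p = 0.00267), DDB2 2.68-fold (1.42 ± 0.07, adjusted p = 0.000267) and MDM2 2.51-fold (1.33 ± 0.13, adjusted p = 0.00433). CENPF fell 2.89-fold (-1.53 ± 0.16, adjusted p = 0.00666) and BIRC5 2.33-fold (-1.22 ± 0.13, adjusted p = 0.00713). TOP2A and CDK1 also fell (adjusted p = 0.0121 and 0.00715). TOP2A was at background on the irradiated arrays at 8 h and 24 h and CDK1 at 24 h, and with such values set to the background limit they were at -1.33 and -1.12.

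Among the 33 genes that rose, 14 were on the p53 list. SPATA18, a regulator of mitochondrial quality, rose 2.83-fold, TNFRSF10C 2.51-fold and RPS27L 1.70-fold. Outside the list, the ligand gene TNFSF9 (4-1BB ligand) rose (adjusted p = 0.0214; at 1.80 with values at background set to the background limit), the surface antigen gene LY6D 2.82-fold (adjusted p = 0.0267), and the pseudogene ANKRD20A8P 2.78-fold (adjusted p = 0.0152). The heparan sulfatase gene SULF2 rose 2.40-fold (adjusted p = 0.0426) and TYMS 1.77-fold (adjusted p = 0.0327). FAS at 1.53 (adjusted p = 0.0591) and GDF15 at 0.31 (adjusted p = 0.0624) did not pass, and rose in the fit with the placenta as block (adjusted p = 1.47e-05 and 0.0109). In that fit 246 genes rose and 235 fell, with 33 of the 246 on the p53 list and 24 of the 235 on the G2 and mitosis list. BAX at 0.51 and TP53 itself at 0.06 passed in neither.

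Of the 53 p53 targets 52 were higher over the 3 times, with a median of 0.51 (adjusted p = 1.66e-48; adjusted p = 0.00124 with an estimated correlation); 14 rose over all genes and 35 adjusted over the list alone. The G2 and mitosis list had 37 of 39 members lower and a median of -0.79 (adjusted p = 5.42e-49; adjusted p = 0.00426 with an estimated correlation), or -0.61 with values at background set to the background limit. This call too ended with the block and an estimated correlation together (adjusted p = 0.0678). Of these, 13 fell over all genes and 31 adjusted over the list alone. The hyaluronan receptor HMMR fell 2.62-fold, and the spindle checkpoint kinases BUB1B and BUB1, PBK and CCNA2 fell as well (adjusted p between 0.0168 and 0.0496 for the 5). The latter 4 were at background on the irradiated arrays at 24 h; with such values set to the background limit BUB1B was at -1.30, BUB1 at -1.10 and CCNA2 at -1.15. For PBK and, outside the list, the kinetochore gene SPC25 (adjusted p = 0.0402) no fold is given, since both sides were at background at 24 h. Also outside the list, the centromere histone chaperone HJURP was at least 3.02-fold lower (adjusted p = 0.0332), the dopamine transporter gene SLC6A3 fell 2.52-fold (adjusted p = 0.0114) and TRIB3 1.40-fold (adjusted p = 0.0215). CCNB1 at -0.36 and MKI67 at -0.24, both on the list, did not pass.

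Smaller list changes over the 3 times lost their call with an estimated correlation. NF-kB and cytokine genes had a median of 0.19 with 17 of 20 higher (adjusted p = 9.33e-05; adjusted p = 0.368 with an estimated correlation), 0 members over all genes and 3 adjusted over the list alone. In the fit with the placenta as block 5 of them rose, among them LIF at 1.28 (with values at background set to the background limit), CXCL1 at 0.73, IL6 at 0.59 and RELB at 0.42 (adjusted p = 0.0214, 0.0114, 0.0262 and 0.0319). Interferon-stimulated genes had a median of -0.30 with 23 of 24 lower (adjusted p = 5.63e-05; adjusted p = 0.549 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. The list was not called without the irradiated 8 h array of placenta 2 (adjusted p = 0.0598). The S phase list was at -0.12 with 26 of 30 lower (adjusted p = 3.2e-05; adjusted p = 0.306 with an estimated correlation); TYMS rose over all genes, and 1 member rose and 1 fell adjusted over the list alone. Double-strand break repair genes were at -0.08 with 23 of 28 lower (adjusted p = 0.00337; adjusted p = 0.321 with an estimated correlation), 0 passing over all genes or adjusted over the list alone. That call ended without the sham 4 h array of placenta 1 (adjusted p = 0.0788), the irradiated 4 h array of placenta 2 (adjusted p = 0.0536) or the irradiated 8 h array of placenta 2 (adjusted p = 0.0598). It also ended with the normexp correction (adjusted p = 0.0595).

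The differentiation genes of the trophoblast did not pass over the 3 times: CGA, the alpha subunit of chorionic gonadotropin, was at -0.03, the fusion protein gene ERVW-1 (syncytin-1) at -0.06, the aromatase gene CYP19A1 at -0.13 and HLA-G at 0.09, and VIM, the intermediate filament of stromal cells, at -0.05. The direction of all of these but CYP19A1 turned when single arrays were left out, in fits that held no placenta term. The syncytiotrophoblast list had a median of 0.01 (adjusted p = 0.706), villous cytotrophoblast genes 0.00 (mean -0.05, adjusted p = 0.951), extravillous genes 0.06 (adjusted p = 0.395), and cell death genes outside the p53 list 0.00 (adjusted p = 0.706). The oxidative stress list was at 0.08 (adjusted p = 0.0568), hypoxia genes at 0.03 (adjusted p = 0.336), the unfolded protein and ATF4 list at 0.01 (mean -0.01, adjusted p = 0.957) and heat shock genes at 0.01 (adjusted p = 0.951). The medians of the remaining lists of processes were 0.03 for immediate early genes (adjusted p = 0.306) and 0.09 for histone genes (mean -0.003, adjusted p = 0.483). Markers of other cells did not pass either. Fibroblast markers were at 0.01 (adjusted p = 0.336, although ACTA2 is on that list) and endothelial markers at -0.04 (adjusted p = 0.944). Macrophage and leukocyte markers were at 0.02 (adjusted p = 0.706), erythroid markers at 0.07 (adjusted p = 0.706) and decidual and amnion markers at -0.04 (mean -0.01, adjusted p = 0.925).

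By limma 910 genes had an unadjusted p under 0.05 over the 3 times, and 27 of the 52 calls were at least 2-fold. The fit with the placenta as block called 481 genes and the fit with the slide as a covariate 94. The normexp correction also gave 52 genes, of which 75% were higher, against 63.5% here. The fits with an array left out held no placenta term, so the difference between the placentas entered each of them. Every array left out lowered the count of 52: to 19 without the sham and 20 without the irradiated 4 h array of placenta 1, 31 and 29 without its 8 h arrays (sham first), and 27 and 21 without its 24 h arrays. For placenta 2 the counts were 29 and 36 without the 4 h arrays, 23 and 28 without the 8 h arrays, and 27 and 22 without the 24 h arrays. Of the 27 genes named here that passed, 11 did so without each array in turn: ACTA2, BIRC5, CDK1, CDKN1A, CENPF, DDB2, EDA2R, FDXR, MDM2, RPS27L and TNFRSF10C.

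The calls at the single times overlapped in part. EDA2R and DDB2 rose at both 4 h and 8 h, against 0.00365 genes by chance, and in the fit with the placenta as block 41 genes were shared (39 higher, against 0.295 by chance, and 2 lower, against 0.0358). In that fit 12 genes were shared between 4 h and 24 h and 21 between 8 h and 24 h (16 higher, 5 lower). The numbers by chance assume independent calls and can be too low. The comparisons share the 2 placentas and each gene's estimate of spread. Across all genes, which are not independent, log2 differences correlated with r = 0.369 between 4 h and 8 h, 0.192 between 4 h and 24 h and 0.357 between 8 h and 24 h.

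Whether the response differed between times was tested directly. The rise of p53 targets was smaller at 24 h than at 4 h: 46 of 53 had a lower log2 difference, with a median of -0.43 (adjusted p = 9.14e-16; adjusted p = 0.0278 with an estimated correlation). It was -0.50 in placenta 1 and -0.28 in placenta 2, where both times were on slide 2. Over all genes 0 members passed, and 3 adjusted over the list alone. MDM2 was at -1.28 ± 0.31, TNFRSF10B at -1.25 ± 0.20, EDA2R at -1.10 ± 0.27, CDKN1A at -0.93 and AEN at -0.84 ± 0.22 (n = 2 arrays in each of 4 groups), none of which passed. By limma 0 genes passed in this comparison, with 257 at an unadjusted p under 0.05. With the placenta as block 3 genes fell, MDM2 (adjusted p = 0.0215), the chemokine CXCL11 at -2.35 (adjusted p = 0.0167) and VASN, a binder of transforming growth factor beta, at -1.12 (adjusted p = 0.0215), the latter 2 chosen after their values were seen. Without the sham 24 h array of placenta 2, TRIM66 passed, chosen after its values were seen, with the remaining sham array at background.

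Other lists also differed between 24 h and 4 h, and each of these calls was lost with an estimated correlation. Interferon-stimulated genes had a median of -0.67, with 24 of 24 lower (adjusted p = 8.72e-10; adjusted p = 0.316 with an estimated correlation), -0.73 in placenta 1 and -0.66 in placenta 2. NF-kB and cytokine genes were at -0.30 (adjusted p = 3.71e-05), G2 and mitosis genes at -0.18 (adjusted p = 4.22e-06) and histone genes at 0.21 (adjusted p = 5.8e-05), each with adjusted p = 0.316 with an estimated correlation. Cell death genes outside the p53 list were at -0.14 (adjusted p = 0.0193; adjusted p = 0.211 with an estimated correlation). Without the block, no member of these lists passed over all genes or adjusted over the list alone. With the placenta as block 0 passed over all genes. Adjusted over the list alone in that fit, 9 interferon-stimulated genes, 5 G2 and mitosis genes, 3 NF-kB and cytokine genes and 1 cell death gene fell. BIRC5 was at -1.11, CDK1 at -0.96 (with values at background set to the background limit) and PTTG1 at -0.71, and outside the lists CIPC was at 0.72, SMC5 at 1.27, ZBTB7A at 0.87 and TMEM52 at -0.76. The NF-kB call ended without the irradiated 24 h array of placenta 1 (adjusted p = 0.125), the histone call without the sham 4 h array of placenta 2 (adjusted p = 0.0646) and the G2 and mitosis call with the normexp correction (adjusted p = 0.0888). The cell death call ended without the sham (adjusted p = 0.0508) or the irradiated (adjusted p = 0.0597) 4 h array of placenta 1, or those of placenta 2 (adjusted p = 0.0644 and 0.0675). It ended as well without the irradiated 24 h array of placenta 1 (adjusted p = 0.14) or the sham 24 h array of placenta 2 (adjusted p = 0.0593).

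The irradiation effect was also compared between 8 h and 4 h. G2 and mitosis genes were lower at 8 h by a list median of -0.28 (adjusted p = 1.66e-09; adjusted p = 0.401 with an estimated correlation), and p53 targets by -0.14 (adjusted p = 0.00128; adjusted p = 0.401 with an estimated correlation). NF-kB and cytokine genes were lower by -0.27 (adjusted p = 0.000239; adjusted p = 0.442 with an estimated correlation). Histone genes were at 0.23 (adjusted p = 0.00128; adjusted p = 0.622 with an estimated correlation) and interferon-stimulated genes at -0.19 (adjusted p = 0.0492; adjusted p = 0.999 with an estimated correlation). Without the block, no member of these lists passed, over all genes or adjusted over the list alone. With the placenta as block 2 p53 targets rose and 5 fell adjusted over the list alone, and no member of the other lists passed. TOP2A was at -1.35 with values at background set to the background limit, TNFRSF10B at -0.75 and ACTA2 at 1.12. By limma 0 genes passed, also with the placenta as block; 110 and 587 genes had an unadjusted p under 0.05 without and with the block. The block added calls for the syncytiotrophoblast list, with a median of 0.15 (adjusted p = 0.00877), and heat shock genes, with -0.07 (adjusted p = 0.0211). Both were lost with the block and an estimated correlation (adjusted p = 0.634 and 0.359).

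Single arrays ended most list calls between 8 h and 4 h. The fits with an array left out held no placenta term, so the difference between the placentas entered them. The p53 call was lost without the irradiated 4 h array of placenta 1 (adjusted p = 0.34), the sham 4 h array of placenta 2 (adjusted p = 0.0778) or the irradiated 8 h array of placenta 2 (adjusted p = 0.298). The NF-kB call was lost without the sham 4 h array of placenta 1 (adjusted p = 0.245). The histone call was lost without the irradiated 4 h (adjusted p = 0.207) or sham 8 h array (adjusted p = 0.345) of placenta 1 or the sham 4 h (adjusted p = 0.307) or irradiated 8 h array (adjusted p = 0.189) of placenta 2. For interferon-stimulated genes the direction turned without the sham 8 h array of placenta 1 (median 0.24) or the irradiated 8 h array of placenta 2 (0.22). For these genes the medians within placenta 1 and placenta 2 were -0.16 and -0.20. Their call also ended without the irradiated 4 h array of placenta 1 (adjusted p = 0.477), the sham 4 h array of placenta 2 (adjusted p = 0.346), either sham 24 h array (adjusted p = 0.0576) or either irradiated 24 h array (adjusted p = 0.0568). Without the sham 8 h array of placenta 1, 4 genes passed, ALKBH1 at 3.75, PDCL at 3.57, SECISBP2 at 3.71 and EVI5L, whose remaining sham array was at background, all chosen after their values were seen. Without a trend in the variance prior OR4K17 passed (adjusted p = 0.0477).

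The sham cells were compared between 24 h and 4 h to show what time in culture changes without irradiation. In all, 746 genes rose and 866 fell, 572 of these at least 2-fold. CYP1A1, an enzyme of xenobiotic metabolism induced through the aryl hydrocarbon receptor, fell 32.4-fold (log2 -5.02 ± 0.62, n = 2 arrays per group, adjusted p = 0.0042). The gene for pancreatic polypeptide, PPY, fell 12.3-fold (-3.62 ± 0.40, adjusted p = 0.00257) and its pseudogene PPY2P was at least 15.3-fold lower (adjusted p = 0.00275). HAMP, which encodes the iron hormone hepcidin, rose 6.47-fold (2.69 ± 0.30, adjusted p = 0.00279) and the adhesion receptor gene ADGRL3 7.29-fold (2.87 ± 0.29, adjusted p = 0.00195).

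Further genes with large rises were the receptor kinase gene ALK (at least 5.76-fold), MTMR7 (at least 5.83-fold), ZSWIM5 (at least 4.20-fold), KCNJ5 (at least 4.72-fold) and CRYBB1 (at least 5.03-fold). The adenosine receptor gene ADORA3 rose by 2.68 on the log2 scale, the channel gene PKD2L1 by 2.60, GAL3ST4 and OLFML3 by 2.39 and the G protein gene GNG11 by 2.35. Among the largest falls were IGFL1 (at least 7.97-fold), DNER (at least 7.07-fold), ZNF365 (at least 5.72-fold) and SHCBP1 (at least 5.49-fold). The oxysterol receptor gene GPR183 fell by 3.21 on the log2 scale, SFN (14-3-3 sigma) by 3.16, thymidine kinase TK1 by 3.04 and the histone gene H3C15 by 2.99.

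Proliferation genes fell with time in sham cells. Of 39 G2 and mitosis genes 38 were lower, with a median of -1.19 (adjusted p = 5.4e-19; adjusted p = 0.101 with an estimated correlation), -1.07 in placenta 1 across slides and -1.45 in placenta 2 within slide 2. Of these, 23 fell over all genes, 32 adjusted over the list alone and 34 with the placenta as block, among them CDK1 (-2.08 ± 0.22), BIRC5 (-2.04 ± 0.22), PTTG1 (-1.51 ± 0.12), CCNB2 (-1.12 ± 0.12) and MKI67 (-1.18 ± 0.25). S phase and replication genes were lower at 25 of 30, with a median of -0.87 (adjusted p = 1.32e-07; adjusted p = 0.192 with an estimated correlation). Of these, 14 fell over all genes, and 15 fell and 1 rose adjusted over the list alone. Among those that fell were TYMS at -2.44 ± 0.21, CDC45 at -2.11 ± 0.13 and the licensing factor CDT1 at -2.08 ± 0.21. With the normexp correction the medians of the 2 lists were -0.65 and -0.44.

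Syncytiotrophoblast genes rose with time, with a median of 0.35 (adjusted p = 0.0071; adjusted p = 0.622 with an estimated correlation); 8 rose and 4 fell over all genes, and 10 rose and 4 fell adjusted over the list alone. The pregnancy-specific glycoproteins PSG1 (1.55 ± 0.10), PSG9 (1.55 ± 0.15) and PSG8 (1.48 ± 0.13) rose, although probes for this family can bind its other members, and the steroid sulfatase STS (-1.14 ± 0.15) fell. CGA at 0.38, ERVW-1 at -0.15 and CYP19A1 at 0.07 did not pass; the 3 probes for CYP19A1 disagreed, from -0.68 to 0.12. Within slide 2, in placenta 2, the list median was 0.26, and with the slide as a covariate 0.03 (adjusted p = 0.447). The call ended without the sham 4 h array of placenta 1 (median 0.005, adjusted p = 0.272) or the sham 24 h array of placenta 2 (adjusted p = 0.0986).

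Villous cytotrophoblast genes, the markers of the progenitor layer, fell with a median of -0.46 (adjusted p = 0.00821; adjusted p = 0.336 with an estimated correlation); 7 fell and 1 rose over all genes and adjusted over the list alone. The cadherin CDH1 fell by 1.22 on the log2 scale, NPNT by 1.57 and the keratins KRT8 and KRT7 by 0.54 and 0.49. With the submitters' matrix the median was -0.19 (adjusted p = 0.0572). Extravillous genes had a median of 0.01 and a mean of -0.17 (adjusted p = 0.619), with 4 up and 4 down: ERBB2 rose by 1.14 and the transcription factor ASCL2 by 0.95, and TIMP3 fell by 0.66 and the deiodinase DIO2 by 1.17. HLA-G was at 0.01.

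The lists of NF-kB and cytokine genes, immediate early genes and oxidative stress genes fell in sham cells. The first had a median of -0.69 (adjusted p = 0.00241; adjusted p = 0.431 with an estimated correlation), with 5 down and 1 up over all genes and 7 down and 1 up adjusted over the list alone; IL1B fell by 2.59, IL32 by 2.52 and CXCL1 by 1.67, and CCL2 rose by 0.82. Immediate early genes were at -0.55 (adjusted p = 0.000384; adjusted p = 0.431 with an estimated correlation), with 4 down over all genes (FOSL1 -2.19, CCN2 -2.06, SRF -1.66, MYC -0.72) and 7 adjusted over the list alone. Oxidative stress genes were at -0.46 (adjusted p = 0.00681; adjusted p = 0.138 with an estimated correlation), with 3 down (GPX3 -2.07, AKR1B10 -1.79, SOD2 -1.68) and 1 up (GPX1 0.47) over all genes, and 4 down and 1 up adjusted over the list alone. In the unfolded protein and ATF4 list (median 0.09, adjusted p = 0.644) the chaperones HSPA5 and PDIA4 fell by 1.15 and 1.14, and PSAT1 and TRIB3 rose by 1.24 and 0.99. In that list 4 rose and 3 fell over all genes, and 5 rose and 4 fell adjusted over the list alone.

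Markers of other cells also moved with time in sham cells. Macrophage and leukocyte markers rose with a median of 0.49 (adjusted p = 0.0071; adjusted p = 0.431 with an estimated correlation). Of these, 6 rose over all genes, and 8 rose and 2 fell adjusted over the list alone. CD163 was at 1.52 ± 0.13, FCER1G at 1.01 ± 0.13, CD14 at 0.96 ± 0.15 and TYROBP at 0.65 ± 0.10. Decidual and amnion markers fell with a median of -0.93 (adjusted p = 0.0071; adjusted p = 0.431 with an estimated correlation), with 4 down over all genes and adjusted over the list alone: SFN, and the keratins KRT6A (-1.42), KRT14 (-1.29) and KRT17 (-1.27). That call ended without the sham 4 h array of placenta 1 (adjusted p = 0.0643). PECAM1 (1.09) rose among endothelial markers (median 0.03, adjusted p = 0.491) and the collagen gene COL5A2 fell by 1.11 among fibroblast markers (median -0.36, adjusted p = 0.294). Erythroid markers had a median of -0.64 (adjusted p = 0.231) and were called with the placenta as block (adjusted p = 0.023). So were interferon-stimulated genes (0.37, adjusted p = 0.067 and 0.0177) and heat shock genes (0.28, adjusted p = 0.0638 and 0.049), of which HSPA1A, HSPH1 and HSPD1 rose by 0.75, 0.55 and 0.53. With the block and an estimated correlation the erythroid, interferon and heat shock calls were lost (adjusted p = 0.316, 0.672 and 0.253).

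The other lists were not called in sham cells. P53 targets had a median of -0.07 (adjusted p = 0.866), with 4 up and 4 down over all genes and 6 up and 5 down adjusted over the list alone; TNFRSF10B rose by 0.97 and ANKRA2, a cofactor of histone deacetylases, by 0.65, PERP fell by 1.10, and the serpin SERPINB5 was at least 3.59-fold lower. The median of this list was 0.05 with quantile normalization. Repair genes had a median of 0.17 and a mean of -0.04 (adjusted p = 0.487); RAD54L, CHEK1 and BLM fell by 2.28, 1.05 and 0.84, and RAD50 rose by 1.01. Histone genes had a median of 0.11 and a mean of -0.08 (adjusted p = 0.829), with H4C3 down by 0.83 and H2AC13 at least 5.74-fold lower. Cell death genes had a median of -0.004 and a mean of 0.02 (adjusted p = 0.579), with BCL2L11, MLKL and CASP1 up by 0.92, 0.92 and 0.81 and BNIP3L down by 0.53. Hypoxia genes had a median of -0.14 (adjusted p = 0.552), with ADM down by 0.52.

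**Figure D4:**
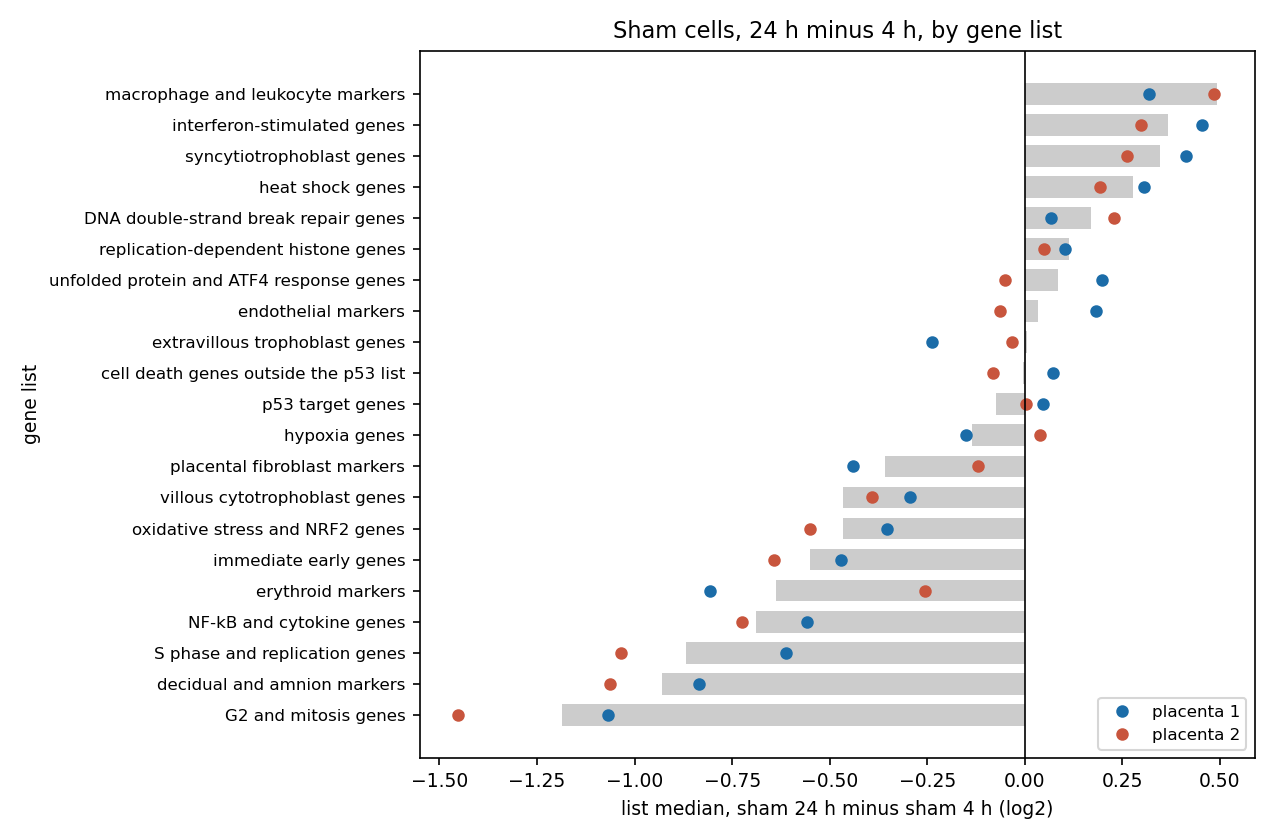
Median log2 difference between the sham arrays at 24 h and at 4 h over the members of each gene list, with 1 point per placenta. G2 and mitosis genes are at -1.07 and -1.45 and S phase genes at -0.61 and -1.04, and the G2 and mitosis list has the lowest median of all lists in both placentas.

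With the placenta as block 2798 genes rose and 2675 fell between the sham cells at 4 h and 24 h, and with the slide as a covariate 1945 rose and 2123 fell. The fits with an array left out, given next, held no placenta term, so the difference between the placentas entered them. The count of 1612 fell to 723 without the sham 4 h array of placenta 1, 224 without that of placenta 2, 676 without the sham 24 h array of placenta 1 and 242 without that of placenta 2. Of the called genes 46.3% were higher, against 57.4% with quantile normalization and 56.1% with the submitters' matrix. CDK1, BIRC5, CCNB2, TYMS, CDC45, CDT1, CD163, HAMP, CYP1A1 and HSPA5 were among those that passed without each array in turn.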

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

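The tests of the 2 patterns weighed here were set before their results were seen; the test of probes without a gene symbol and the test of p53 targets that were not higher in sham cells were chosen after the result was seen.

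The fall of interferon-stimulated genes at 24 h stood out because the irradiation effect on this list differed between times: by -0.67 in log2 between 24 h and 4 h and by -0.187 between 8 h and 4 h. Both calls were lost with an estimated correlation (adjusted p = 0.316 and 0.999). The latter difference turned without the sham 8 h array of placenta 1 (0.238) or the irradiated 8 h array of placenta 2 (0.222). Those fits held no placenta term, so leaving out 1 array let the difference between the placentas into the comparison. Within placenta 1 and placenta 2 the medians of that difference were -0.156 and -0.202. The fall at 24 h is relative to sham cells, in which the list itself was higher at 24 h than at 4 h. Its sham median was 0.368, with 20 of 24 members higher (adjusted p = 0.067, and 0.0177 with the placenta as block). With the block and an estimated correlation that call was lost (adjusted p = 0.672). The sham change is a term of the difference between 24 h and 4 h. The -0.67 is therefore not a fall of that size in irradiated cells. A loss of leukocytes from the irradiated cultures would have lowered their markers. The mean of the macrophage and leukocyte list at 24 h was -0.075 (SE over members 0.071). The interferon list was at -0.652, and the limit for that explanation was -0.326. Members of the leukocyte list ranged from -0.949 to 0.393, and it pools macrophage and lymphoid markers. Its mean argues against a loss of leukocytes as a whole and cannot tell whether 1 cell type among them was lost. The scaling of the arrays was argued against as well, since the median nearest 0 under 3 other scalings was -0.657. Against a difference in 1 placenta stood the pair nearer 0, with a median of -0.678 (SE over members 0.059). Errors over members treat the genes of a list as independent and hold no spread between arrays. Each placenta therefore gives only 1 value here. No biological explanation other than the loss of leukocytes was tested, and the list's call at 24 h was lost with an estimated correlation (adjusted p = 0.424). The position of arrays on the slide, where irradiated and sham arrays alternated, and a difference in cell number or secreted interferon between cultures were not tested.

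The p53 target response was smaller at 24 h than at 4 h, by a list median of -0.429. Each irradiated array shared its slide with its sham partner, so a slide effect equal on both arrays cancels in this difference. Only a slide effect that differed between treatments was left to test. If such an effect in placenta 1 had caused this, placenta 2 would not have shown it. The median of placenta 2 was -0.282 (SE over members 0.059) within slide 2. The errors in this paragraph are over list members and hold no spread between arrays, and placenta 2 gives 1 value. Under the 3 other scalings the value nearest 0 was -0.345, and in sham cells the list did not rise between 4 h and 24 h (median -0.074, SE 0.084, against the 0.215 such a cause would need). Members went both ways there, and 25 of 53 were higher, so that a sham rise enters the difference of such genes as TNFRSF10B, which rose by 0.97. Among the 28 that were not higher in sham cells the median difference was -0.323 (SE 0.076), and among the 25 that were higher -0.497 (SE 0.078). The sham change is a term of this difference, so the split cannot tell how much of its size comes from the sham cells. A response that declines within a day is consistent with these values, as a hypothesis, and it can be followed in MDM2, which is both a target and an inhibitor of p53. Loss of the most damaged cells from the culture would give the same values and was not tested.

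Other lists called between times are given as values, and each of these calls was lost with an estimated correlation (adjusted p = 0.211 to 0.316 between 24 h and 4 h, and 0.401 to 0.622 between 8 h and 4 h). Between 24 h and 4 h the differences were -0.183 for G2 and mitosis genes and 0.211 for the histone list. They were -0.136 for cell death genes outside the p53 list and -0.304 for NF-kB and cytokine genes. Between 8 h and 4 h they were -0.138 for p53 targets, -0.28 for G2 and mitosis genes, 0.226 for histone genes and -0.267 for NF-kB and cytokine genes.

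Probes without a gene symbol, which no comparison of named genes used, also responded. Over the 3 times 28 of 6736 such probes passed, 27 of them higher (384 with an unadjusted p under 0.05, and 61, 57 of them higher, with the placenta as block). Of the 28, 17 were annotated as long intergenic RNAs on hg19, as were 3249 of the 6736 tested. Several of those that passed lie in overlapping intervals on chromosomes 1 and 4, so that probes do not count separate transcripts. Those chosen here, after their values were seen, lie on chromosome 1 from 142840948 to 142842761 (log2 1.52 ± 0.11, adjusted p = 0.000836) and on chromosome 4 from 90602655 to 90605092 (1.79 ± 0.19, adjusted p = 0.00344). A further 2 lie on chromosome 6 from 48044816 to 48070216 (1.74 ± 0.18, adjusted p = 0.00344) and on chromosome 1 from 9233849 to 9234611 (1.42 ± 0.15, adjusted p = 0.00344). A second probe for the last interval was at 1.09 ± 0.20 and did not pass (adjusted p = 0.0677).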

How the results depend on the processing

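The normexp version on median signals, the exact sign-flip test and the test of unnamed probes were chosen after the result was seen; the other alternatives were planned. Quantile normalization, the submitters' matrix, the normexp correction, the filters, every probe tested and the variance prior without a trend kept every total count over all genes within 1.5 times, except that without a trend 1 gene passed at 24 h and 1 in the 8 h minus 4 h difference, against 0. Counts by direction moved more. Over the 3 times 31 genes rose and 8 fell with the filter on all 12 arrays, against 33 and 19. The 39 list calls had 1047 values, the reported ones included. Of these, 899 kept direction and side of the threshold under an alternative, 2 reversed, and the remaining alternatives lost the call. The 235 gene results named (1 gene in 1 comparison each) had 5796 values, the reported ones included. Of these, 4698 kept both, 672 lost the call, 162 gained one and 29 reversed. The cause of these moves was not tested, save where fewer arrays leave less to estimate the spread from. The fits with an array left out also held no placenta term, so the difference between the placentas entered their comparisons. With an array left out, the lone array of its group is assumed to vary like the other groups. Signal near background limits the G2 and mitosis list, with 15 of 39 members at background on one side or both at 24 h.

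With the placenta as block the counts were 91, 79 and 42 genes at 4, 8 and 24 h, 481 over the 3 times (841 with the 6 pairs as blocks in an additive fit), 3 for the 24 h minus 4 h difference and 5473 in sham cells. All calls made without the block were kept; 64 of the values of named genes passed in addition, and beyond the lists named in the report it changed no call of a list. The overlaps were then 41, 12 and 21 genes (4 h with 8 h, 4 h with 24 h, 8 h with 24 h). Without the block, 5 genes were shared between 4 h and 8 h at an adjusted p under 0.10. With the slide as a covariate the counts were 24, 24 and 2, then 94 over the 3 times and 4068 in sham cells; with both, 373, 180 and 250, then 1333, 10 for 24 h minus 4 h and 6398. The arrays of slide 2 alone gave 0 at 4 h, 1 at 8 h, 0 over the 3 times, 1 for 8 h minus 4 h and 0 in sham cells. Only the arrays compared gave 0 at 4 h, 0 at 8 h and 0 in sham cells. With so few residual degrees of freedom these say nothing about stability. The gene at 8 h was EVI5L, chosen after its value was seen, whose sham array was at background. Of the 39 list calls, 9 held with an estimated correlation (p53 targets in all 4 comparisons with sham and between 24 h and 4 h, G2 and mitosis genes in those 4). With the block and an estimated correlation together, G2 and mitosis genes were not called in those 4 (adjusted p = 0.0622 to 0.178). The test fry, which does not compare a list with other genes, made 19 calls. With the placenta as block, fry called G2 and mitosis genes in those 4 comparisons (adjusted p = 0.000391 to 0.0203). The exact two-sided sign-flip test over the 6 pairs cannot go below p = 0.03125, which 6 lists reached, p53 targets and G2 and mitosis genes among them (adjusted p = 0.109).

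Leaving out each array gave 0 to 9 genes at 4 h, 0 to 12 at 8 h, 0 to 1 at 24 h, 19 to 36 over the 3 times, 0 to 1 for 24 h minus 4 h, 0 to 4 for 8 h minus 4 h and 224 to 1442 in sham cells, and 35 to 47 list calls. Interferon-stimulated genes between 8 h and 4 h ranged from -0.515 to 0.238. Over the 3 times the ranges were -0.044 to 0.156 for TP53, -0.175 to 0.12 for CGA (0.016 on slide 2 alone), -0.136 to 0.011 for ERVW-1, -0.039 to 0.223 for HLA-G and -0.124 to 0.016 for VIM, none of them called. In sham cells they were -0.372 to 0.068 for ERVW-1, -0.129 to 0.27 for CYP19A1 and -0.387 to 0.401 for HLA-G. The latter 2 were at -0.149 and -0.337 with the slide as a covariate, at -0.006 and -0.221 with placenta and slide, and at -0.129 and -0.387 on slide 2 alone. None of these was called except HLA-G with placenta and slide (adjusted p = 0.0443).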

Other observations

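The genes in the first 2 paragraphs and the slide test of the sham cells were chosen after the result was seen. In the fit with the placenta as block, irradiated trophoblasts had further changes at 4 h and 8 h outside the named lists. The proliferation clamp PCNA rose at 4 h and 8 h (log2 0.96 and 1.04, adjusted p = 0.00586 and 0.00546), as did RRAD, a small GTPase (1.34 and 0.97, adjusted p = 0.0031 and 0.0237). PLAU, the urokinase gene, rose at both times (1.03 and 0.64, adjusted p = 0.00233 and 0.0402), and so did TNFSF9 (2.00 and 2.14, adjusted p = 0.0241 and 0.018) and the interleukin 21 receptor gene IL21R (1.46 and 1.84, adjusted p = 0.0233 and 0.00806). At 4 h the chemokine gene CCL3 (0.91, adjusted p = 0.0241) and the NF-kB regulators BCL3 (0.91, adjusted p = 0.0346) and NFKBIE (0.51, adjusted p = 0.0437) rose. HAMP, which rose with time in sham cells, fell after irradiation by 0.74 at 4 h and 0.61 at 8 h (adjusted p = 0.00233 and 0.0101). The histone H4 genes H4C13 and H4C2 fell by 0.54 each at 8 h (adjusted p = 0.012 and 0.0119).

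At 24 h in the same fit CXCL11, a chemokine induced by interferon gamma, fell by 1.96 (adjusted p = 0.00331), LAMP3, a lysosomal membrane protein, by 0.86 (adjusted p = 0.0393) and IFI35, an interferon-induced protein, by 0.66 (adjusted p = 0.0394). The skeletal muscle actin gene ACTA1 fell by 0.94 (adjusted p = 0.0255), the myosin light chain gene MYL9 by 0.69 (adjusted p = 0.0389) and NPPB, which encodes B-type natriuretic peptide, by 1.09 (adjusted p = 0.0256), while ACTA2 rose at 1.42 (adjusted p = 0.0386). Among the genes that rose were G0S2, an inhibitor of lipolysis, at 1.04 (adjusted p = 0.0245), the transcription factor MLXIPL by at least 4.43-fold (adjusted p = 0.0368), DCSTAMP, a protein of cell fusion, at 0.99 (adjusted p = 0.0256), and the receptor TREM2 at 0.55 (adjusted p = 0.0418).

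Between 4 h and 24 h in sham cells the G2 and mitosis list fell by a median of 1.19 on the log2 scale, which was weighed against 2 technical explanations. The slides of the placenta 1 arrays were argued against by placenta 2, where both times shared a slide and the median was -1.453 (SE over members 0.109). That error holds no spread between arrays, since placenta 2 had 1 sham array per time. The scaling of the arrays changed the size, to -0.653 with the normexp correction, which lies beyond the -0.593 that scaling as the main cause would need. No biological explanation was tested, and neither was a loss of cycling cells of another type. With an estimated correlation the list was not called (adjusted p = 0.101).

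Chance as the source of the genes called over the 3 times was tested by regrouping the arrays. In an additive fit with time, 4 of 100 drawn splits of the 462 gave as many genes as the 61 of the real split, that split included; the highest other gave 1498. That split put 5 of the 6 arrays of placenta 1 and 3 of the 4 arrays of slide 1 together, so it points to a structure of the samples, the placenta or the slide, which this fit does not take into account. Among the 32 splits that part all 6 irradiated and sham pairs, with the pairs as blocks, only the real split reached its 841 genes. The highest other gave 1. The smallest share this test can reach is 1 of 32, so chance is made less likely there but is not excluded. The real split also follows the array columns, which this test cannot part from treatment.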
